A study of Homo sapiens with 6 samples.

How the data were processed

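Total RNA of 6 samples of cells labelled as BxPC3 was analysed, 3 untreated and 3 treated with dauricine for 72 h, each on 1 single-colour Agilent array. The labels give 24 µmol of dauricine and state neither a volume nor a vehicle control, and no replicate was described as a separate culture. The RNA was amplified and labelled with Cy3 by the authors, and the arrays were read with Agilent Feature Extraction 11.0.1.1. The intensity values are, per the file headers, the software's processed signal of each spot, which is background-subtracted and detrended within its array and not scaled between arrays. The deposited values of each sample are log2 values, 1 per probe, whose column medians lie at 6.33 for all 6 samples, and the authors do not state how they were normalized. Each column correlated best, across probes, with the array of its own sample (Pearson r from 0.993 to 0.9998). The probe annotation in the files names build hg19, while the reference table of symbols belongs to GRCh38.p14, so that it was used for names alone and no coordinates are given.

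The arrays held 43118 spots of 34127 probes that were not controls. Symbols were taken by matching the RefSeq accession of each probe, without its version, to the reference table: 25771 probes matched, of which 79 of XIST or Y-linked genes were left out, leaving 25692, and 8356 had no match. Spots marked by the software as uneven or as population outliers were left out, and the spots of a probe were averaged. Main values were log2 of the processed signal minus the array's 75th percentile over these probes. Probes had to stand well above background, by the software's flag, on at least 3 of the 6 arrays, which 25913 did, 20640 of them with a symbol. A gene was represented by the brightest of its probes over all arrays, giving 16295 genes, of which 47 had an array left out. Of 3666 genes with several tested probes, 8 had probes called in opposite directions (ARFGEF3, BCL2L11, GPSM1, MAP4, MLPH, MUC2, SCARF2 and TBXA2R). None of them is named below for a direction. They stayed in the gene counts and, where listed, in the list tests by their brightest probe. No spot was saturated.

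Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, moderated test, two-sided) and version 1.17.8 of the data.table package. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and an absolute log2 change of at least 1. Errors of changes are standard errors from this fit. There were 33 gene lists, written before the data were examined, with 779 entries, of which 15 had no matched probe and 9 genes stood on more than 1 list. Lists were tested with camera in limma against all other genes at a preset correlation of 0.01, with at least 5 measured members, and adjusted over the lists. Camera with an estimated correlation, and fry, were run beside it. The list of p53 target genes and that of pro-apoptotic genes share BBC3, and the marker lists of other pancreatic cells, fibroblasts, leukocytes and endothelial cells served to show RNA of other cells. A gene counted as measured in 1 group only when its probe was well above background on all arrays of that group and on none of the other; its bound is the mean of the measured group over the mean, per array, of the lowest signal among probes above background in the other. Genes with a spot left out in the dim group were excluded from this count, a choice made after their bounds were seen to be wrong.

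The genes named were chosen by a rule set before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, that were above background on all 6 arrays and that had a proper gene symbol. Of these falls, 1 is not described. From each list it took the 2 called members with the largest change in the direction of most called members, and the 1 with the largest change the other way. A list without a called member gave the member with the smallest p. Of genes measured in 1 group only it took the 3 highest bounds in each direction. Any other gene is said to have been chosen after its values were seen.

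On simulated data with the same spread, the gene test recovered 61% of genes changed by 1.5 and 95% of genes changed by 3 on the log2 scale, with 8 false calls among the unchanged of 16248 genes and 0 when nothing was changed. The list test recovered the mitosis list lowered by 1 and called 0 others. The simulated genes varied independently of each other, so this does not show how often lists are called falsely on the real arrays. There the estimated correlation within a list reached 0.91 (metallothioneins), and the other splits of the 6 arrays called 6 to 12 lists. The replicate numbers did not pair the samples: the correlation across genes of residuals between arrays of the same number was -0.24, -0.23 and -0.05. Dauricine replicates 1 and 2 were much alike, with a spread of log2 differences among bright genes of 0.138, against 0.0906 expected from spot noise and 0.299 to 0.466 between other arrays of a group. They were kept as separate samples, so the n of 3 in the dauricine group may overstate the number of independent samples.

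The alternatives set before the data were examined were quantile normalization, scaling to the median, no scaling, normexp background correction with an offset of 50, no filter on dim probes, a filter on all 6 arrays, outlier spots kept, the mean of a gene's probes, the deposited value table, a replicate block, trended and robust variance, array weights, an unequal-variance test, treat, and leaving out each array. Cyclic loess normalization and the averaging of dauricine replicates 1 and 2 were chosen after seeing the data. The files hold no mean spot signal, so normexp used the median spot signal and the local background. In a first fit, outlying local backgrounds distorted 1 array, so these were replaced by the array's median background, after that result was seen. A slide block could not be fitted, because each of the 2 slides held 1 group. The 10 splits of the 6 arrays into 3 and 3 were refitted in the same way.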

Results

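RNA levels were measured on 6 single-colour oligonucleotide arrays in cells labelled as BxPC3, an established human pancreatic adenocarcinoma line. Signals of CDKN2A and MAP2K4, reported as deleted in this line, leave that label in doubt, as described at the end. A difference of cells between the groups, if there was one, could not be told apart from treatment in any comparison below. There were 3 samples of untreated cells and 3 samples of cells treated for 72 h with dauricine, a plant alkaloid, at an amount that the labels write as 24 µmol with no volume. On the untreated arrays 27457, 26239 and 26721 of the 34127 probes stood well above background, and on the dauricine arrays 22773, 23718 and 22025 did. The 75th percentile of the processed signal was 898, 560 and 840 intensity units in replicates 1 to 3 of the untreated cells and 483, 502 and 470 in those of the dauricine cells. Local background averaged 25.3 ± 0.58 units (SD, n = 3) on the slide that held the untreated arrays and 39.2 ± 0.76 (SD, n = 3) on the slide that held the dauricine arrays, so slide and treatment cannot be told apart in any comparison below. The number of arrays limits the precision of every value. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between samples, which may be technical.

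The comparison of dauricine with untreated cells asks how dauricine affected gene expression in a pancreatic carcinoma line. DDIT3, which encodes the stress-induced transcription factor CHOP, rose most among the genes above background on all 6 arrays, taken by each gene's brightest probe, by 4.09 ± 0.27 on the log2 scale (SE, n = 3 per group, adjusted p = 0.000283), or 17.1-fold. Its partner TRIB3, a pseudokinase gene induced by CHOP, rose by 3.32 ± 0.34 (adjusted p = 0.00238). The other large rises were those of IL1RL1, the interleukin-33 receptor gene (3.67 ± 0.67), the G protein subunit gene GNB4 (3.26 ± 0.19), LAMP3, which encodes a lysosome-associated membrane protein (3.20 ± 0.51), the basement membrane collagen gene COL4A2 (3.17 ± 0.20), RASIP1, whose product binds Ras-family proteins (3.14 ± 0.19), and USP18, which encodes the protease that removes ISG15 from proteins (3.11 ± 0.86). Large falls were those of the potassium channel subunit gene KCNG4 (-3.15 ± 0.28), the hypocretin precursor gene HCRT (-2.98 ± 0.55), the chemokine gene CXCL14 (-2.78 ± 0.43), the cell-cycle transcription factor gene E2F2 (-2.50 ± 0.28), SPMAP2 (-2.33 ± 0.19), the ankyrin gene ANK2 (-2.31 ± 0.27) and the aldehyde dehydrogenase gene ALDH1A1 (-2.30 ± 0.44). Adjusted p ran from 0.000221 for GNB4 to 0.0464 for USP18, and the values of the 2 groups did not overlap for any of these genes. Without untreated replicate 1 the adjusted p of IL1RL1, LAMP3, USP18, HCRT, CXCL14 and ALDH1A1 became 0.0663, 0.0558, 0.148, 0.0699, 0.0504 and 0.0776, and these calls were lost. That of USP18 was lost in 5 of the 6 fits that left out 1 array and that of ALDH1A1 also without untreated replicate 3, at an adjusted p of 0.0563. IL1RL1, LAMP3, USP18, HCRT, CXCL14 and ALDH1A1 each lay closest to the untreated mean in dauricine replicate 3. In dauricine replicates 1 to 3 the log2 signal of IL1RL1 was 1.08, 1.26 and -1.54, against an untreated mean of -3.398. That of LAMP3 was 3.59, 3.59 and 1.66 (untreated mean -0.25) and that of CXCL14 0.301, 0.225 and 1.93 (untreated mean 3.599). TRIB3 and KCNG4 changed most in replicate 3.

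Of 16295 genes tested, 557 were called higher and 992 lower in dauricine cells, 1549 in all, at an adjusted p under 0.05 and a change of at least 2-fold. At the adjusted p alone there were 1051 higher and 1556 lower. The groups did not overlap for 1543 of the called genes and for 40.2% of all genes tested, against 10% by chance. Falls outnumbered rises mainly among dim genes: 503 of the 992 falls lay among the 3259 dimmest genes, where the median change of all genes was -0.48, while among the 3259 brightest genes, with a median change of 0.21, there were 141 rises and 65 falls. In 359 of the genes called lower, the probe stood above background on no dauricine array, so the size of their fall is not known. In all, 806 genes were above background in untreated cells only. Against the lowest signal above background, their median fall was at least 1.06-fold, and only 38 had a bound of 2-fold or more. Among genes above background on all 6 arrays the calls were 482 higher and 518 lower. Without untreated replicate 1 there were 539 calls (235 higher, 304 lower), without dauricine replicate 2 there were 921 (332 higher, 589 lower), and without dauricine replicate 3 there were 2204 (977 higher, 1227 lower). The higher calls also fell to 368 without untreated replicate 3 and to 349 without dauricine replicate 1. The share of rises among the calls depended on the scaling between arrays, 36.0% as reported, 46.8% after quantile normalization, 53.3% after scaling to the median and 3.27% without scaling, and on the background correction, 63.3% with normexp.

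**Figure D1:**
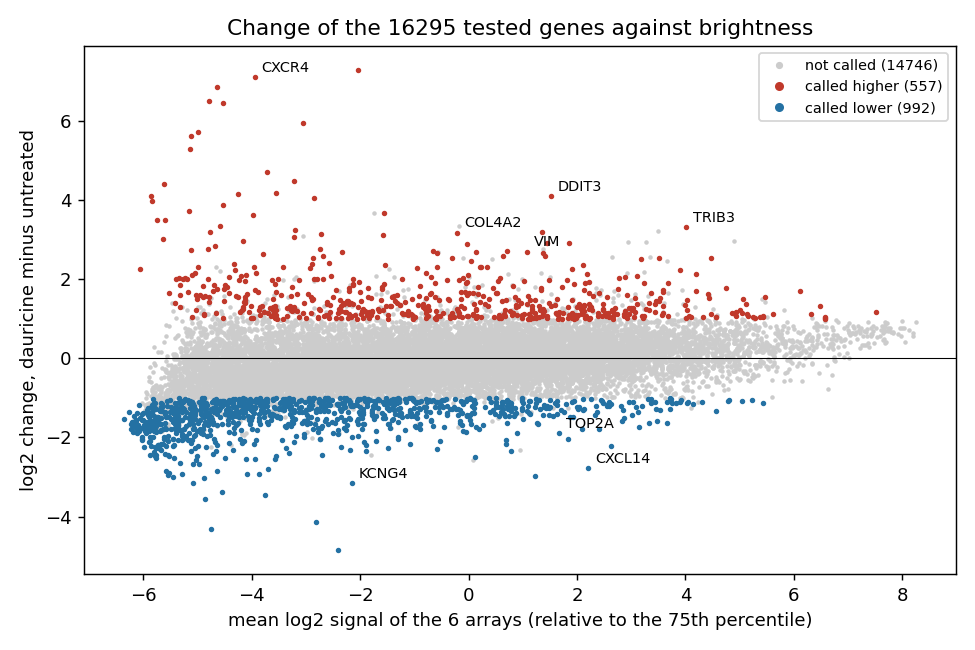
Log2 change (dauricine minus untreated, vertical axis) of each of the 16295 genes tested against its mean log2 signal over the 6 arrays relative to each array's 75th percentile (horizontal axis), with 557 genes called higher in red, 992 called lower in blue and the others in grey. The falls crowd at the dim end on the left, where 503 of the 992 lie among the 3259 dimmest genes.

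Genes of cell division were lower in dauricine cells. On the mitosis list 20 of 34 measured members fell and 0 rose (21 fell when adjusted over the list alone), with a median change of -1.09 (adjusted p = 3.1e-14; adjusted p = 0.397 with an estimated correlation). TOP2A, the DNA topoisomerase gene of dividing cells, fell by 1.89 ± 0.18 (SE, n = 3 per group) and the mitotic kinesin gene KIF20A by 1.88 ± 0.34. On the DNA replication list 18 of 41 members fell and 0 rose (also 18 when adjusted over the list alone), with a median change of -0.91 (adjusted p = 2.5e-12; adjusted p = 0.397 with an estimated correlation). The origin licensing genes CDC6 and ORC1 fell by 1.67 ± 0.45 and 1.53 ± 0.24, CDC6 on 2 dauricine arrays above background. On the list of homologous recombination and Fanconi repair 10 of 23 members fell and 0 rose (also 10 when adjusted over the list alone), with a median change of -0.84 (adjusted p = 3.2e-05; adjusted p = 0.193 with an estimated correlation). The exonuclease gene EXO1 fell by 2.0 ± 0.25 and the Fanconi anaemia gene FANCD2 by 1.65 ± 0.21. These falls were seen in all 3 dauricine replicates, whose mitosis medians against the untreated mean were -0.93, -0.95 and -1.51. The calls of KIF20A and CDC6 were lost without untreated replicate 1, at adjusted p of 0.0666 and 0.128. CDC6 also lost its call without untreated replicate 2 or 3 or dauricine replicate 2, at adjusted p up to 0.103, and after quantile normalization. With normexp the falls of CDC6, ORC1 and FANCD2 shrank to 0.19, 0.65 and 0.81, and none of them was called.

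The stress response driven by ATF4 and CHOP was higher. Of its 28 measured genes 13 rose and 0 fell (15 rose when adjusted over the list alone), with a median change of 1.02 (adjusted p = 1.4e-11; adjusted p = 0.193 with an estimated correlation), and DDIT3 and TRIB3 led them. The 3 dauricine replicates had medians of 0.75, 0.95 and 1.30 against the untreated mean. The list of ER chaperones and the unfolded protein response was higher as well, with 2 of 24 members called higher and 0 lower (4 higher when adjusted over the list alone), a median change of 0.53 and replicate medians of 0.26, 0.24 and 0.72 (adjusted p = 7.0e-05; adjusted p = 0.623 with an estimated correlation). HERPUD1, which takes part in the degradation of misfolded ER proteins, rose by 1.37 ± 0.22 (SE, n = 3 per group). The ER co-chaperone gene DNAJB9 rose by 1.31 ± 0.31. The DNAJB9 call was lost without any 1 of the untreated replicates or without dauricine replicate 2, at adjusted p from 0.0546 to 0.0870. Neither gene was called in the deposited table, at rises of 0.99 and 1.15, or without scaling, at 0.74 and 0.68. The autophagy list had 3 of 27 members called higher and 0 lower (also 3 when adjusted over the list alone) and a median change of 0.22, with replicate medians of 0.31, 0.44 and 0.11 (adjusted p = 0.0056; adjusted p = 0.623 with an estimated correlation). WIPI1, an early autophagosome protein gene, rose by 1.57 ± 0.24 and MAP1LC3B, which encodes the autophagosome marker LC3B, by 1.31 ± 0.18. The autophagy call was lost without untreated replicate 2, with normexp background correction and after cyclic loess, at medians of 0.27, 0.19 and 0.13 and adjusted p of 0.0599, 0.214 and 0.0668. The median shrank in the last 2 only.

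Genes of cholesterol synthesis and uptake and genes induced by interferon were far higher in dauricine replicates 1 and 2 but not in replicate 3. The 24 cholesterol genes had medians of 2.35, 2.47 and -0.03 in the 3 replicates against the untreated mean, and an overall median change of 1.66 (adjusted p = 6.0e-07; adjusted p = 0.623 with an estimated correlation). Only ACAT2, an acetyl-CoA acetyltransferase gene, was called, at 2.66 ± 0.71 (SE, n = 3 per group), with 0 members lower and 6 higher when adjusted over the list alone. Without dauricine replicate 3, 20 of the 24 were called higher, and the ACAT2 change was 3.60 ± 0.26. The 33 interferon-stimulated genes had medians of 2.50, 2.78 and -0.26, and an overall median of 1.67 (adjusted p = 4.5e-07; adjusted p = 0.629 with an estimated correlation). USP18 and IFI6, the latter at 2.91 ± 0.60, were called higher and 0 members lower (1 higher when adjusted over the list alone), against 28 higher without dauricine replicate 3. The 8 metallothioneins, metal-binding stress proteins, had medians of 1.41, 1.31 and -0.61, an overall median of 0.68 and 1 called member, MT1G at 1.05 ± 0.21 (also 1 when adjusted over the list alone, and 0 lower; adjusted p = 0.0356; adjusted p = 0.642 with an estimated correlation). Without dauricine replicate 3, 6 of them were called higher. Without any 1 of the other 5 arrays the metallothionein list was not called, at adjusted p from 0.0538 to 0.143, nor after quantile normalization, scaling to the median, normexp or cyclic loess, at 0.0654 to 0.347.

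The calls of single genes on these lists depended on which arrays were in the fit. ACAT2 and USP18 lost their calls when any 1 array other than dauricine replicate 3 was left out, at adjusted p from 0.0867 to 0.127 and from 0.0827 to 0.148. IFI6 lost its call without any 1 of the untreated replicates, at 0.0522 to 0.0867, and MT1G without untreated replicate 1 or 2 or dauricine replicate 1 or 2, at adjusted p up to 0.0749. Fatty acid synthesis genes were higher too. Of the 15 measured 4 rose and 0 fell (7 rose when adjusted over the list alone), with a median change of 1.05 and replicate medians of 1.22, 1.29 and 0.26 (adjusted p = 0.00023; adjusted p = 0.397 with an estimated correlation). LPIN1, a phosphatidate phosphatase gene, rose by 2.32 ± 0.33 (SE, n = 3 per group) and PNPLA3, a lipid droplet protein gene, by 2.16 ± 0.18, above background on 2 of the 3 untreated arrays. Without dauricine replicate 3, 9 of the 15 rose.

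**Figure D2:**
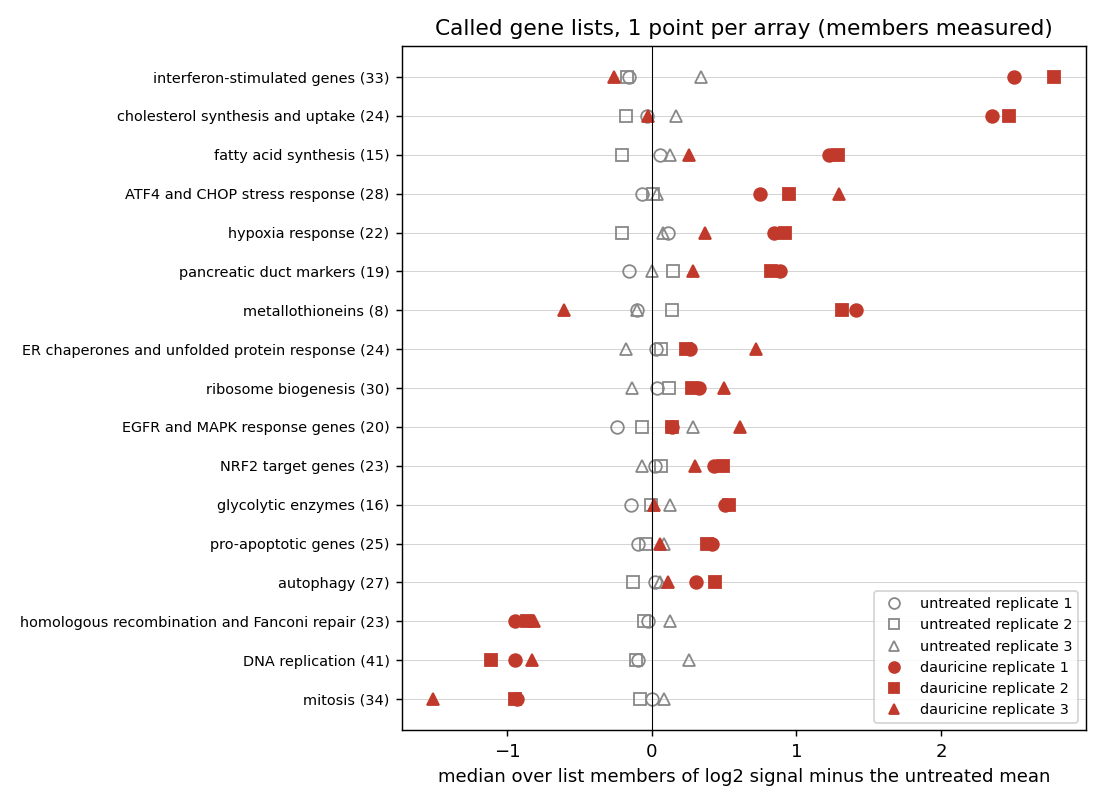
Median over the members of each of the 17 called gene lists (number of members measured in brackets) of the log2 signal minus the mean of the untreated arrays (horizontal axis), with 1 point per array, untreated arrays in open grey and dauricine arrays in filled red. Dauricine replicate 3 (triangles) lies with the untreated arrays for interferon-stimulated genes (-0.26) and cholesterol genes (-0.03) and with the other dauricine arrays for DNA replication and repair.

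Hypoxia response genes were higher: 4 of 22 rose and 0 fell (7 rose when adjusted over the list alone), with a median change of 0.82 and replicate medians of 0.84, 0.92 and 0.37 (adjusted p = 9.5e-07; adjusted p = 0.397 with an estimated correlation). Without dauricine replicate 3, 9 of them rose. BNIP3, a mitochondrial protein gene induced by low oxygen, rose by 4.47 ± 0.23 (SE, n = 3 per group, above background on 2 untreated arrays), and the collagen prolyl hydroxylase gene P4HA1 by 1.97 ± 0.36. The glycolytic enzyme list had 1 of 16 members called higher, the enolase gene ENO2 at 1.53 ± 0.23, and 0 lower (also 1 when adjusted over the list alone). Its replicate medians were 0.50, 0.53 and 0.02, so the rise was absent in dauricine replicate 3. The overall median of 0.30 (adjusted p = 0.0185; adjusted p = 0.642 with an estimated correlation) turned to -0.10 after quantile normalization, and the list was not called without untreated replicate 1 or 2, at adjusted p of 0.0561 and 0.0532. Of the 23 genes induced by NRF2, the oxidative stress regulator, 3 rose and 0 fell (also 3 when adjusted over the list alone), with a median of 0.32 and replicate medians of 0.43, 0.49 and 0.30 (adjusted p = 0.00055; adjusted p = 0.397 with an estimated correlation). The haem oxygenase gene HMOX1 rose by 1.35 ± 0.24 and the sulfiredoxin gene SRXN1 by 1.15 ± 0.17. The rise of SRXN1 was 0.97 after quantile normalization, 0.94 in the deposited table, 0.97 after cyclic loess and 0.52 without scaling, and was not called there. The NRF2 list was not called after quantile normalization (median 0.18), in the deposited table or after cyclic loess, at adjusted p of 0.0637, 0.0682 and 0.0911. The calls of P4HA1, ENO2 and HMOX1 were lost without untreated replicate 1, at adjusted p of 0.0601, 0.0501 and 0.0547.

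Ribosome biogenesis genes had 2 of 30 members called higher and 0 lower (also 2 when adjusted over the list alone), with a median of 0.36 and replicate medians of 0.33, 0.28 and 0.50 (adjusted p = 0.00055; adjusted p = 0.589 with an estimated correlation). They were the nucleolar protein genes GNL3, at 1.22 ± 0.24 (SE, n = 3 per group), and WDR43, at 1.20 ± 0.21. The list call was lost with normexp, in the deposited table and after cyclic loess, at adjusted p of 0.0544, 0.0503 and 0.0752. Genes that respond to EGFR and MAPK signalling had 6 of 20 members called higher and 1 lower (the same numbers when adjusted over the list alone), with a median of 0.32 and replicate medians of 0.14, 0.14 and 0.61 (adjusted p = 0.0247; adjusted p = 0.629 with an estimated correlation). DUSP5, a phosphatase gene that restrains ERK, rose by 2.03 ± 0.35 and the AP-1 gene FOSL1 by 1.62 ± 0.25, while FOS fell by 1.75 ± 0.34. Among 25 pro-apoptotic genes 2 rose and 2 fell (the same numbers when adjusted over the list alone), with a median of 0.23 and replicate medians of 0.41, 0.38 and 0.05 (adjusted p = 0.0220; adjusted p = 0.637 with an estimated correlation). BBC3, which encodes PUMA, rose by 1.73 ± 0.27 and BIK by 1.15 ± 0.20, and the apoptosome gene APAF1 fell by 1.24 ± 0.23, above background on 1 dauricine array. The fall of APAF1 was 0.95 after quantile normalization, 0.998 in the deposited table, 0.76 after cyclic loess and 0.13 with normexp, and was not called in any of these. Of 19 pancreatic duct markers 2 rose and 0 fell (4 rose and 2 fell when adjusted over the list alone), with a median of 0.81 and replicate medians of 0.89, 0.83 and 0.29 (adjusted p = 0.0028; adjusted p = 0.477 with an estimated correlation). CEACAM5, an adhesion molecule gene, rose by 1.35 ± 0.27 and the osteopontin gene SPP1 by 1.30 ± 0.25. After cyclic loess the duct list was not called (adjusted p = 0.0511).

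Several of these calls were lost when 1 array was left out. The call of the EGFR and MAPK list was lost without dauricine replicate 3 (median 0.11, adjusted p = 0.319) or untreated replicate 2 (median 0.41, adjusted p = 0.0532), and that of the pro-apoptotic list without untreated replicate 2 or dauricine replicate 2 (medians of 0.34 and 0.19, adjusted p of 0.0629 and 0.0613). Both were also lost after quantile normalization, at medians of 0.28 and 0.14, with normexp, without the filter on dim probes, in the deposited table and after cyclic loess, at adjusted p from 0.0647 to 0.303. Without untreated replicate 1 the adjusted p of DUSP5, FOS, BBC3, BIK, APAF1, CEACAM5 and SPP1 became 0.0501, 0.0594, 0.0522, 0.0597, 0.0652, 0.0796 and 0.0696, past the threshold. GNL3 lost its call without untreated replicate 3 or dauricine replicate 1 or 2, at adjusted p of 0.0522 to 0.0631. FOS (without untreated replicate 3), BIK (without dauricine replicate 2), and CEACAM5 and SPP1 (without dauricine replicate 1 or 2) were lost in other such fits too, at adjusted p of 0.0513 to 0.0598. In all these fits the change of each of these 8 genes kept its direction and stayed above 2-fold, so it was the adjusted p and not the size that ended the calls. Of the 73 named genes that were called, 33 stayed called in all 6 fits that left out 1 array.

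The other 16 lists were not called. The intermediate filament gene VIM rose by 2.70 ± 0.20 (SE, n = 3 per group, adjusted p = 0.000491), and ZEB1, a repressor of epithelial genes, by 1.19 ± 0.30. They stood on the mesenchymal transition list, where 3 of 25 rose and 0 fell (4 rose when adjusted over the list alone; list adjusted p = 0.347). On the epithelial junction list 1 of 21 rose and 2 fell (the same numbers when adjusted over the list alone; list adjusted p = 0.448). The desmosomal cadherin gene DSG3 fell by 1.79 ± 0.24 and the tight junction gene CLDN1 by 1.1 ± 0.23, while the polarity gene CRB3 rose by 1.24 ± 0.27. On the squamous differentiation list 1 of 22 rose and 2 fell (2 rose and 3 fell when adjusted over the list alone; list adjusted p = 0.958). S100A8 and LY6D fell by 1.23 ± 0.34 and 1.05 ± 0.27, and the kallikrein gene KLK5 rose by 1.09 ± 0.27. Without untreated replicate 1 the calls of ZEB1, CLDN1, CRB3, S100A8, LY6D and KLK5 were lost, at adjusted p of 0.0797 to 0.119, and each was lost in at least 3 further fits of this kind, at adjusted p up to 0.130.

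Inflammatory genes moved both ways. On the list of NF-kappaB and inflammatory cytokines 2 of 25 rose and 2 fell (3 and 3 when adjusted over the list alone; list adjusted p = 0.569): the cytokine genes IL11 and IL1B rose by 2.53 ± 0.53 and 1.38 ± 0.26 (SE, n = 3 per group) and the chemokine gene CXCL1 fell by 2.04 ± 0.32. Among 23 p53 target genes 1 rose and 2 fell (the same numbers when adjusted over the list alone; list adjusted p = 0.541): TP53INP1 and the translesion polymerase gene POLH fell by 1.38 ± 0.30 and 1.17 ± 0.28, and BBC3 rose by 1.73 ± 0.27. The translation repressor gene EIF4EBP1 rose by 1.05 ± 0.20, the 1 called member of 27 PI3K, AKT and mTOR components, where 0 fell (1 and 0 when adjusted over the list alone; list adjusted p = 0.448). Its rise was 0.75 after quantile normalization, 0.73 in the deposited table, 0.73 after cyclic loess, 0.98 with normexp and 0.42 without scaling, and was not called in any of these. Of 19 genes of drug metabolism and efflux 1 fell, the aldehyde dehydrogenase gene ALDH3A1 by 1.62 ± 0.41, and 0 rose (0 and 0 when adjusted over the list alone; list adjusted p = 0.366). Without untreated replicate 1 the calls of IL11, IL1B, CXCL1, TP53INP1, POLH, BBC3, EIF4EBP1 and ALDH3A1 were lost, at adjusted p of 0.0505 to 0.0965. ALDH3A1 was also lost without each other array except dauricine replicate 3, at adjusted p up to 0.103. POLH was also lost without untreated replicate 3 or dauricine replicate 1 or 2, EIF4EBP1 without untreated replicate 3 or dauricine replicate 1, TP53INP1 without untreated replicate 3 and IL11 without dauricine replicate 2, at adjusted p up to 0.0952. Over the mean of each gene's probes TP53INP1 and POLH fell by 0.85 and 0.50 (adjusted p = 0.0789 and 0.135), and with normexp by 0.87 and 0.48, so both calls rested on the brightest probe and on the background correction.

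The remaining marker lists covered other pancreatic cells and cell types that a pure culture should lack. Among 12 pancreatic acinar markers 1 fell, the elastase gene CELA3A by 1.48 ± 0.28 (SE, n = 3 per group), and 0 rose (1 and 0 when adjusted over the list alone; list adjusted p = 0.678). Among 9 pancreatic islet markers 2 fell and 0 rose (the same numbers when adjusted over the list alone; list adjusted p = 0.261). They were the transcription factor gene PAX6 and the prohormone convertase gene PCSK1, both above background on 0 dauricine arrays. The size of their falls is therefore not known, and with normexp neither was called (-0.09 and 0.17). Of 9 fibroblast and stellate markers 2 rose and 2 fell (2 rose and 4 fell when adjusted over the list alone; list adjusted p = 0.985): COL1A1 and S100A4 rose by 1.22 ± 0.19 and 1.15 ± 0.19, and the proteoglycan gene DCN fell by 2.0 ± 0.40. Of 15 leukocyte and 7 endothelial markers 0 were called in limma (0 adjusted over the list alone; list adjusted p = 0.426 and 0.527), and 8 and 2 reached an unadjusted p under 0.05. CD3E had a change of 0.93 ± 0.20 and VWF of -0.62 ± 0.23. The calls of CELA3A, PCSK1 and DCN were lost without untreated replicate 1, at adjusted p of 0.0554, 0.0533 and 0.0813, and DCN was lost without untreated replicate 2 as well, at 0.0545.

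The remaining lists held 0 called members in limma, over all genes and adjusted over the list alone. The lysosome list had a median change of -0.02 over 34 genes (list adjusted p = 0.630), with 6 at an unadjusted p under 0.05, among them the cholesterol transporter gene NPC1 at 0.77 ± 0.17 (SE, n = 3 per group). The oxidative phosphorylation list had a median of -0.08 over 52 genes (list adjusted p = 0.826), with 4 at that p, among them the ATP synthase gene ATP5MC1 at -0.87 ± 0.20. This list was called lower after quantile normalization, which raised the number of lower lists to 4. Lower lists also numbered 4 with normexp, in the deposited table and after cyclic loess. Anti-apoptotic genes had a median of 0.25 over 10 genes (list adjusted p = 0.274), with 2 at that p, among them BCL2L2 at 0.49 ± 0.18. The heat shock list had a median of 0.07 over 19 genes (list adjusted p = 0.678), with 2 at that p, among them the co-chaperone gene BAG3 at -0.89 ± 0.22.

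In all, 14 lists were called higher and 3 lower of 33. With the correlation estimated for each list 0 were called, while 2 reached an unadjusted p under 0.05, the ATF4 and CHOP list and the repair list. In fry, which tests each list by itself, 5 lists were higher (ATF4 and CHOP, fatty acid synthesis, NRF2, hypoxia and pancreatic duct) and 4 lower (mitosis, DNA replication, repair, and drug metabolism and efflux). For the lysosome, NF-kappaB, epithelial junction, mesenchymal and squamous lists the median was below 0 while the list test pointed higher, and for the heat shock list the mean was below 0 while the median and the test were above. Setting members that stood above background in only 1 group to their bounds moved the median of 0 lists by over 0.1.

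**Figure D3:**
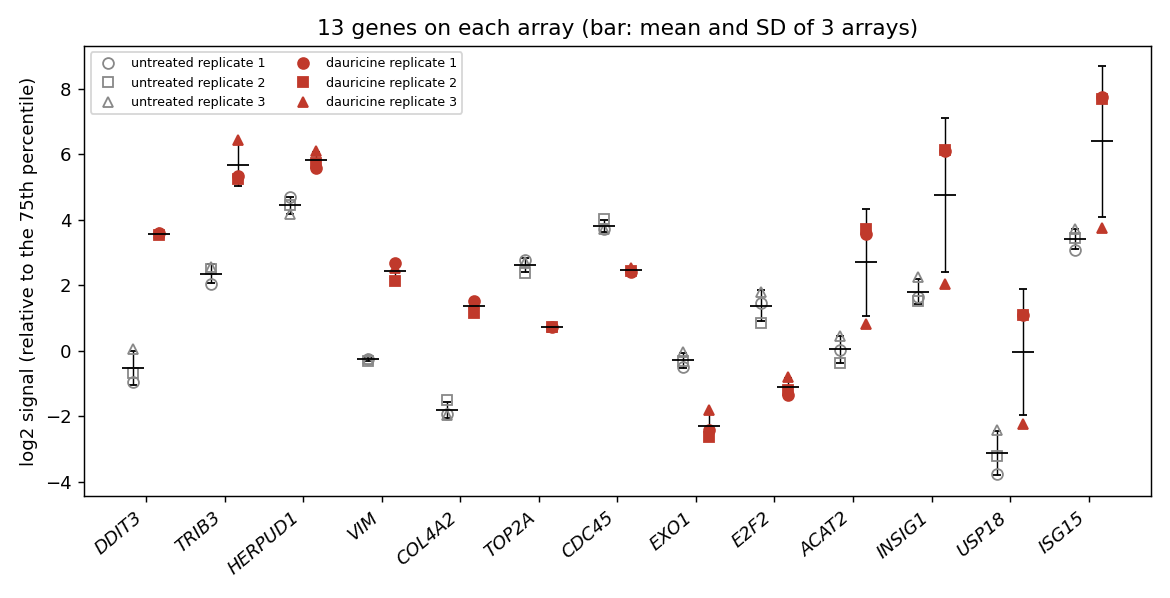
Log2 signal relative to each array's 75th percentile (vertical axis) of 13 genes on each array, untreated in open grey and dauricine in filled red, with black bars for the mean and SD of 3 arrays. CDC45, INSIG1 and ISG15 were added after their values were seen; ACAT2, INSIG1, USP18 and ISG15 are high on dauricine arrays 1 and 2 and near the untreated level on array 3, unlike DDIT3, TRIB3, VIM and TOP2A.

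Some genes could be measured in 1 group only. The chemokine receptor gene CXCR4 was above background on all 3 dauricine arrays and on 0 untreated arrays, at least 50.2-fold higher in dauricine cells against the lowest signal called above background. The neuronal pentraxin gene NPTX1 was at least 28.4-fold higher and the kinase gene MAPK4 at least 26.5-fold higher. In all, 28 genes appeared in dauricine cells only, 10 of them with a bound of 10-fold or more. In the other direction 806 genes were above background on all untreated arrays and on 0 dauricine arrays, but only 38 of these had a bound of 2-fold or more (110 with the other detection flag below). The tight junction gene CLDN8 was at least 7.07-fold lower, the transcription factor gene MYCN at least 5.42-fold lower and CYP4F22, a cytochrome P450 gene, at least 4.72-fold lower. These bounds were computed for the reported background correction and scaling only. The 3558 named probes above background on no untreated array rose by a median of 0.72 on the log2 scale. The bounds are not corrected for such a shift. With normexp the log2 changes were 3.23, 2.76 and 2.68 for CXCR4, NPTX1 and MAPK4 and -1.06, -0.83 and -0.75 for CLDN8, MYCN and CYP4F22, all smaller than the bounds, and the calls of MYCN and CYP4F22 were lost. The normexp offset of 50, added to every signal, itself shrinks changes of dim signals, so these values neither bear out nor refute the bounds. The lowest signal above background was 1.20 higher on the log2 scale, or 2.3-fold, on the dauricine arrays, which raises the second count and lowers the first. With the software's other detection flag, which needs only a positive and significant signal, the counts were 21 and 361.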

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

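The tests of dauricine replicate 3, of the genes above background in dauricine cells only and of the lower cell-cycle genes were chosen after these results were seen; the splits of the samples were planned beforehand.

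Probes that matched no gene symbol were left out of the gene comparison and still gave a signal. Of 5241 such probes tested with limma, 896 were called between the groups, 318 higher and 578 lower in dauricine cells.

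In other splits of the 6 arrays into 3 and 3, limma called 0 genes, with 69 to 1254 genes at an unadjusted p under 0.05 against 5780 in the real split. Of the 10 splits, 1, the real one, gave as many as 1549 changed genes, 1 gave as many as 557 in 1 direction and 1 as many as 992. For lists called in 1 direction, 1 split gave as many as 14 and the highest other gave 12, while all 10 gave at least 3. With 10 splits no share can fall under 0.05. The split with 12 lists set dauricine replicates 1 and 2 with untreated replicate 3.

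Dauricine replicate 3 stood apart from replicates 1 and 2. Of the 57 members of the interferon and cholesterol lists, 94.7% were lower in it than in both others; these lists were picked for that pattern, so this share tests nothing. An untreated sample under a dauricine label stays open. Of the 53 probes gained on dauricine arrays 1 and 2, 66.0% (95% Wilson interval 52.6 to 77.3) were above background on array 3. The share was at most 29.3% (20.2 to 40.4) for an untreated array left out in turn. Dauricine array 3 shared its slide with arrays 1 and 2, and the untreated arrays were on the other slide. A probe gained through the slide would appear on array 3 with any sample, so these shares cannot decide the question. A weaker form of the same response would shift the mitosis genes less in replicate 3. They lay lower in it by a median of -0.53 (bootstrap interval over list members -0.71 to -0.26). By such intervals 5 called lists were shifted further in it, against 9 shifted less. The intervals treat genes as independent, rest on 1 array and measure no spread between samples. The mitosis list was chosen after its medians were seen, so these values describe replicate 3 and do not decide the question. The design names no difference between the replicates, so no biological explanation was tested, and a difference in culture, time or handling stays open.

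The 28 genes above background in dauricine cells only could have come from the higher background on the dauricine slide. For the 10 with a bound of 10-fold or more, the lowest dauricine array exceeded the highest untreated array in raw signal by at least 65 for each. Local background differed by at most 29.5 between the slides (99th against 1st percentile), which argues against background as the source of these 10 signals. These genes were picked for a high dauricine signal, so a large raw difference was likely and shows only that it exceeds the background difference. Of 3526 other probes above background on no untreated array, 4 rose by as much as the smallest of their bounds. The gained genes were left out of those probes, so this count decides nothing. For the other 18, with log2 bounds of 1.55 to 3.06, it stays open as a group: the same raw difference was as small as 8 and above 29.5 in only 5 of them, and 210 of the other probes rose by at least 1.55. For RNA of fibroblasts, leukocytes or endothelial cells, no general rise of their markers was seen. At most 22.2% of the measured members of a marker list were called higher (2 of 9 fibroblast markers). Of the abundant transcripts COL1A2, COL3A1, DCN, PTPRC, PECAM1, CDH5 and VWF had lower means in dauricine cells, though all but COL1A2 and COL3A1 were above background on all dauricine arrays, while COL1A1 went from -4.21 to -2.99. A small share of such RNA need not make many markers pass the threshold, and only 9 of 16 fibroblast markers were measured, so it stays open. RNA of another tumour line stays open: of the genes reported as deleted in BxPC3, SMAD4 was above background on 0 dauricine arrays, as with a line that also lacks it, but MAP2K4 appeared on all 3 with 1 of its 2 probes and both CDKN2A probes rose, by 1.65 and 5.27, which dauricine could not cause in cells that lack these genes; whether the probes lie within the deleted parts was not checked.

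The lower mitosis, DNA replication and repair genes might have followed from the trend of change with brightness. After cyclic loess, which removes such trends, their medians were -1.13, -0.99 and -0.83 in that order, each still past the threshold, with a highest adjusted p of 1.2e-05, which argues against the trend as the whole cause. Another difference between the slides cannot be told apart from dauricine, since each slide held 1 group and local background differed 1.55-fold between them.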

How the results depend on the processing

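Cyclic loess and the averaging of dauricine replicates 1 and 2 were chosen after the data were seen; the other alternatives were planned. The 3 lower lists (mitosis, DNA replication and repair) and 5 of the higher ones (cholesterol, interferon, fatty acid, ATF4 and CHOP, and hypoxia) kept their direction and call in every camera fit at the preset correlation, and 0 lists were called higher or lower with an estimated correlation. Of the 73 named genes that were called, 20 stayed called in every setting that gave their values (the unequal-variance test and treat were run for total counts only), 33 in all fits that left out 1 array, and 39 were lost without untreated replicate 1.

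The calls of genes depended on the scaling and the test. There were 5047 without scaling (165 higher, 4882 lower), where the median of all genes moved to -0.70 against -0.07, and 719 with normexp (264 lower), where it moved to 0.11. Against 557 higher and 992 lower, scaling to the median gave 839 higher and array weights 1089 higher. The filter on all arrays gave 540 lower, with 546 of the called genes not tested. Averaging dauricine replicates 1 and 2 gave 1054 calls (362 higher, 692 lower), and 15 of the named genes lost their call. The unequal-variance test called 18 (10 higher, 8 lower), with 1365 at an unadjusted p under 0.05 and a 2-fold change, and treat, which tests against a 2-fold change itself, called 67 (44 higher, 23 lower). The quantile, loess and deposited values gave 590 and 670, 685 and 697, and 630 and 709 higher and lower, and 67.5%, 69.8% and 70.4% of the called genes stayed called in the same direction. Leaving out 1 array gave 539 to 2204 calls (235 to 977 higher, 304 to 1227 lower), lowest without untreated replicate 1 and highest without dauricine replicate 3. With the replicate block there were 1647 calls (599 higher, 1048 lower) and 14 and 3 lists.

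Higher lists numbered 9 after quantile normalization, 8 with normexp, 8 in the deposited table, 6 after cyclic loess, 5 in fry and 9 to 13 with 1 array left out, against 14. The glycolytic median reversed to -0.10 after quantile normalization, -0.11 in the deposited table, -0.10 after loess and -0.33 without scaling. Without scaling the medians of autophagy (-0.41), ER chaperones (-0.10), NRF2 (-0.31), ribosome biogenesis (-0.27), EGFR and MAPK (-0.31) and pro-apoptotic genes (-0.40) reversed too, all above the shift of -0.70 of all genes. With normexp PCSK1 reversed to 0.17. The cause was not tested for any of these except the shift without scaling and the fewer genes tested. The other detection flag gave 361 genes above background in untreated cells only, against 806. Signal over background limits the dim genes: 359 of the falls rest on dauricine signals below background, so their size is not known.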

Other observations

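The gene families below and the other genes named here were chosen after the values were seen.

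Host genes of small nucleolar RNAs were higher in dauricine cells. Families were formed by the first letters of the symbols, and 12 of 187 passed camera at the preset correlation, 0 with an estimated correlation (adjusted p = 0.944 for each family named here). The 14 SNHG genes had a median log2 change of 0.68 (adjusted p = 0.0036), 4 were called higher, and the replicate medians were 0.78, 0.91 and 0.71. Their median was 0.47 after cyclic loess, 0.48 after quantile normalization, 0.80 after scaling to the median, 0.64 with normexp, and 0.05 without scaling, where the median of all genes was -0.70. The 61 genes grouped by the letters RPL, mostly of the large ribosomal subunit, had a median of 0.67. The 42 grouped by RPS, mostly of the small subunit but not only, had a median of 0.68. These medians shrank to 0.18 and 0.20 after cyclic loess. After quantile normalization they were 0.10 and 0.14, and neither family was called in camera (adjusted p = 0.0708 and 0.168). The 11 MCM genes, mostly helicase subunits of DNA replication, had a median of -0.87, from -0.74 to -0.98 over the other scalings. It was -1.50 without scaling, where the family was not called in camera (adjusted p = 0.0768). The 31 kinesin genes (KIF) had a median of -0.57, with 10 lower and 2 higher, and of -0.13 with normexp. Without scaling it was -1.20, and the family was not called in camera (adjusted p = 0.315). The 18 genes grouped by the letters TAS, mostly taste receptors, had a median of -0.86 that turned to 0.05 with normexp.

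Both probes of CDKN2A, a gene of cyclin-dependent kinase inhibitors, were above background on all 6 arrays and higher in dauricine cells. The brighter went from 1.58 ± 0.39 to 3.23 ± 0.47 and the dimmer from -5.32 ± 0.43 to -0.05 ± 0.31 (log2 signal relative to the 75th percentile, SD, n = 3). MAP2K4, a kinase gene, was above background with 1 of its 2 probes on all dauricine arrays and on 0 untreated arrays, at least 6.68-fold higher. The cancer-testis antigen genes PAGE1 and MAGEA9 were at least 22.7-fold and 14.6-fold higher, and EEF1A2, a translation elongation factor gene, at least 24.9-fold. CDKN2A and MAP2K4 are reported as deleted in BxPC3, so these signals, and that of CDKN2A on the untreated arrays, go against the line label unless the probes lie outside the deleted parts or bind other RNA, which was not checked. Whether the RNA of these genes came from BxPC3 cells was not settled. If the groups held different cells, every call and list above could reflect that difference as well as dauricine.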
